A study of Mus musculus with 24 samples.

How the data were processed

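The series measured RNA on 24 Affymetrix mouse expression arrays. Primary cortical neurons from E18 mice were kept in culture for 1 week and then treated for 2 h or 12 h. The treatments were the solvent DMSO, IBET858 at 1 µM, BDNF at 50 ng per ml, and BDNF with IBET858. IBET858 is an inhibitor of the BET proteins, which bind acetylated histones, and BDNF is a growth factor that signals through the TrkB receptor. The 8 groups held 3 arrays each. The labels number the replicates and do not say whether they came from separate cultures, so p-values measure the spread between these samples only.

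The deposited values are on a log2 scale. Per the submitters' processing notes, the authors made them with RMA, which adjusts background, brings all arrays to 1 distribution and summarises each probe set. RMA works in log2 units, although the table itself does not state the base. The authors' table held 45101 probe sets, 64 of them Affymetrix controls. In the deposited log2 table the median over the 24 arrays was 0 for 45101 of 45101 probe sets, within a tolerance of 1e-06. Each probe set had thus been centred. Centring keeps differences between arrays and removes the level of each probe set, and setting arrays to 1 distribution hides any change in total mRNA per cell. Detection calls, background values and scanner files were not used here. For arrays of this kind the number of arrays limits the precision.

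Probe sets were named from the platform annotation. It listed 35890 of the probe sets, 34958 with 1 gene symbol and 932 with several, and 9211 were not listed. Entrez IDs matched 34754 of the 34958 to the RefSeq gene table of assembly GRCm38.p6, which served only for names and for the order of genes along chromosomes, and 204 did not match. The value of a gene was the mean of all probe sets naming that gene alone, which gave 18194 genes, 9012 of them with more than 1 probe set. No dim genes were removed. Centred values made 3 planned steps impossible: picking the probe set with the highest mean, limiting the analysis to brightly expressed genes, and requiring a minimum level of named genes. The mean of all probe sets had been planned as an alternative and took the first step's place. Gene span was not analysed here beyond a list of very long genes.

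Differential expression was computed with limma 3.58.1 in R 4.3.3. One model held a mean for each of the 8 groups, with 16 residual degrees of freedom and a variance prior from eBayes. The 12 contrasts were IBET858 against DMSO, BDNF against DMSO, both together against BDNF, and both together against IBET858, each at 2 h and 12 h, the interaction of BDNF and IBET858 at each time, and the difference between 12 h and 2 h of the IBET858 effect and of the BDNF effect. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast. A gene was called at an adjusted p under 0.05. Fold changes are given on the log2 scale with the standard error of the model after the ± sign, and n = 3 arrays per group throughout.

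The 33 gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, and adjusted over the lists within a contrast. Camera was repeated with the correlation estimated from the residuals. Members called were counted over all genes and again adjusted over the list alone. The lists covered activity-induced transcription factors and effector genes, MAP kinase feedback regulators, neuropeptides, cholesterol synthesis, glutamate receptors, postsynaptic and presynaptic proteins, GABA genes, voltage-gated channels, very long neuronal genes, autism-associated genes, axon guidance, BET proteins and elongation factors, histones, ribosomal and mitochondrial proteins, interferon, NF-kappaB, endoplasmic reticulum stress, heat shock, p53 targets, cell cycle, clock genes and sex-linked transcripts. Markers of neurons, excitatory neurons, interneurons, astrocytes, progenitors, oligodendrocytes, microglia and vascular cells completed them.

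Named genes followed a rule. For IBET858 against DMSO, BDNF against DMSO and both together against BDNF, the 10 highest and 10 lowest changes were taken at each time among called genes whose arrays did not overlap between the groups. For the other contrasts it was the 5 highest and 5 lowest, and for interactions and differences between times the arrays were not compared for overlap. Predicted and unnamed genes were left out. Up to 4 members per list with the largest change were added, and Bdnf, Fos, Arc, Egr1, Brd2, Brd3, Hexim1, Myc and the sex-linked transcripts in every contrast. A further item of the rule is not reported here. The groups, contrasts, limma and camera tests, lists and naming rule were chosen before the data were examined, and so were the other processing settings named below, except 2. Of the tests of possible explanations for a pattern, some were chosen only after the result was seen, and these are listed with the patterns.

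The agreement of the IBET858 effects with and without BDNF was measured by Pearson correlation across genes, which are not independent replicates, and by shared calls against the number that independent calls would give. Genes raised by BDNF and lower with the inhibitor were counted beside the number that independent calls would give. The pipeline was tested on simulated data with the spread of these arrays. With 100 genes changed by each of 2 sizes, IBET858 against DMSO at 12 h recovered 82 of 100 at a log2 change of 0.5 and 100 of 100 at 1, with 9 false among 191 calls. For the interaction at 12 h it recovered 52 of 100 and 97 of 100, with 9 false among 158 calls. A simulated shift of -0.2 in the very long neuronal genes was called by camera and no other list was. The simulated genes varied independently, so this run could not show false list calls from correlation between genes.

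The other settings tried were median centring of arrays, cyclic loess between arrays, array weights, a trended and robust variance prior, removal of probe sets marked as able to cross-hybridise, fits on the compared groups alone, a replicate block, leaving out each array in turn, and the estimated correlation in camera. After the data were seen, the probe set with the largest variance per gene and a fit without 2 arrays that stood apart were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.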

Results

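RNA was measured on 24 arrays from mouse cortical neuron cultures, 3 arrays for each of 4 treatments at 2 h and at 12 h. The values are log2 intensities centred per probe set, so they show differences between samples and not how abundant a transcript was. Within groups, most arrays lay close together, with a standard deviation around their group mean between 0.072 and 0.117 log2 units. DMSO at 2 h replicate 1 stood apart at 0.178, and IBET858 at 12 h replicate 3 at 0.157. A total of 18194 genes was tested in each comparison, and the number of arrays limits the precision.

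**Figure D1:**
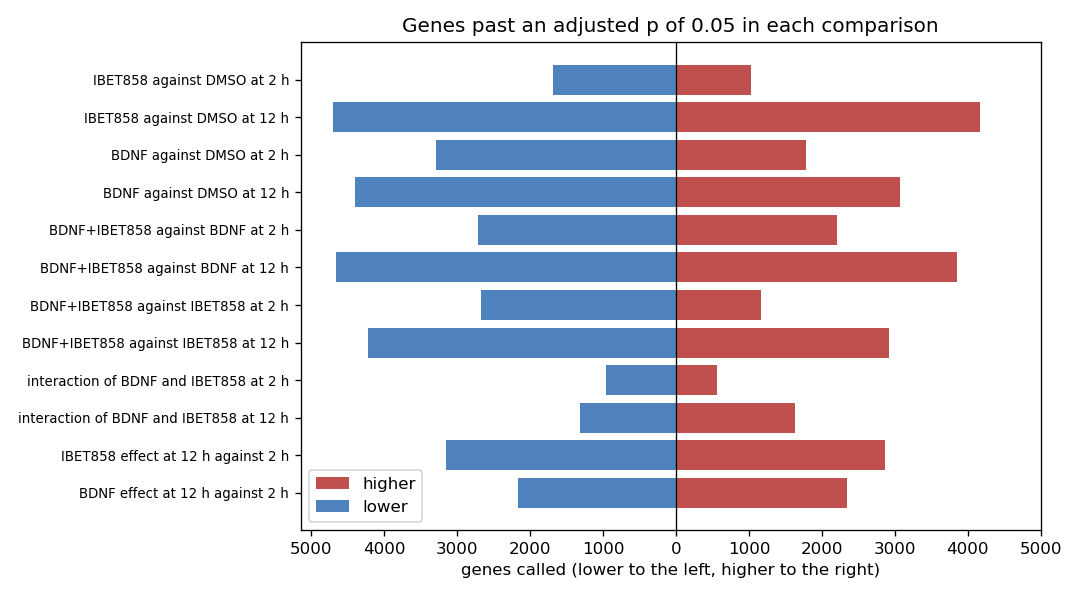
Number of genes called lower (blue, left) and higher (red, right) at an adjusted p under 0.05 in each of the 12 comparisons. IBET858 against DMSO at 12 h has the most calls, 4701 lower and 4162 higher, and the interaction at 2 h the fewest, 963 lower and 566 higher.

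IBET858 against DMSO at 2 h shows what the BET inhibitor does within hours in neurons without added BDNF. Histone genes and the P-TEFb inhibitor Hexim1 were among the genes that rose furthest. H2bc18, a gene for histone H2B, rose by 3.95 ± 0.23 on the log2 scale (15.4-fold), Depdc7 by 2.84 ± 0.14, Fam117a by 2.68 ± 0.15, Hexim1 by 2.48 ± 0.10 and the histone H3 gene H3c4 by 2.43 ± 0.17 (n = 3 per group). Ckmt2, a mitochondrial creatine kinase, rose by 2.13 ± 0.12, Lag3 by 1.97 ± 0.14, Sertad1 by 1.91 ± 0.060, H3c11 by 1.89 ± 0.13 and the chaperone gene Hspa1b by 1.85 ± 0.12. The largest falls were in Mir124a-1hg, the host transcript of a neuronal microRNA (-1.69 ± 0.083), and in Hs3st1, a heparan sulfate sulfotransferase (-1.59 ± 0.053). The zinc finger genes Zfp748 (-1.52 ± 0.12), Zfp551 (-1.51 ± 0.11), Zfp518a (-1.48 ± 0.15) and Zfp11 (-1.41 ± 0.095) fell too. The nuclear receptor gene Nr0b1 (-1.44 ± 0.22), Nup37 (-1.43 ± 0.086), Fastkd5 (-1.40 ± 0.058) and Ttc30a1 (-1.39 ± 0.12) fell by similar amounts. Among the BET genes themselves, Brd2 rose by 0.70 ± 0.057, and Brd3 was at 0.05 ± 0.049 (adjusted p = 0.568).

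Groups of genes moved as well. Of the linker and core histones, 12 of 15 measured members rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.81, camera adjusted p = 1.01e-14, and adjusted p = 0.00398 with an estimated correlation. Copies of 1 histone type are close in sequence, and a probe set can read several of them. Among activity-induced transcription factors, 17 of 32 rose and 4 fell (18 and 4 adjusted over the list alone), including Ier2 at 1.66 ± 0.089, Klf2 at 1.46 ± 0.080, Jun at 1.42 ± 0.066 and Egr1 at 1.33 ± 0.085. For the transcription factors, camera gave adjusted p = 5.11e-09, and adjusted p = 0.144 with an estimated correlation. Fos rose by 0.43 ± 0.073 and Myc fell, at -0.43 ± 0.11, a call lost without DMSO replicate 2 (-0.30, adjusted p = 0.0602). Among activity-induced effector genes, 17 of 38 rose and 1 fell (19 and 2 adjusted over the list alone), with Gadd45b at 1.64 ± 0.087, the neuronal pentraxin Nptx1 at 1.63 ± 0.093 and Arc at 1.42 ± 0.14. For the effector genes, camera gave adjusted p = 9.94e-11, and adjusted p = 0.066 with an estimated correlation. Bdnf itself was at -0.38 ± 0.26 (adjusted p = 0.388). Heat shock genes (6 of 18 rose and 0 fell, 6 and 0 adjusted over the list alone) were led by Hspa1b and Hspa1a (1.43 ± 0.092), with camera adjusted p = 0.000125, and adjusted p = 0.0982 with an estimated correlation. Genes of endoplasmic reticulum and amino acid stress (14 of 35 rose and 0 fell, 16 and 0 adjusted over the list alone) included Ddit3 at 1.15 ± 0.11 and Sesn2 at 0.91 ± 0.17. For these stress genes, camera gave adjusted p = 1.62e-05, and adjusted p = 0.358 with an estimated correlation. On DMSO replicate 1 their median deviation from the other DMSO replicates was -0.419 (other arrays from their own group mates -0.0396 to 0.213). That of the activity-induced transcription factors was -0.331 (others -0.173 to 0.197). A low control array lowers the DMSO mean and so enlarges rises over it.

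In total 2712 genes were called at 2 h, 1026 higher and 1686 lower, of which 244 and 311 changed over 1.5-fold. With array weights the calls were 2948 higher and 2880 lower. Camera also passed the lists of MAP kinase feedback, neuropeptides, cholesterol, GABA genes, axon guidance, ribosomal proteins and interneuron markers, with adjusted p between 0.327 and 0.436 under an estimated correlation. All of these lost their calls in a fit without DMSO at 2 h replicate 1 and IBET858 at 12 h replicate 3, with adjusted p between 0.0894 and 0.313, and the activity-induced effector median moved from 0.30 to 0.14. The ribosomal median of 0.041 turned to -0.0034 with cyclic loess.

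IBET858 against DMSO at 12 h shows the longer effect of the inhibitor. Histones and Hexim1 stayed high, and genes for glutamate receptors and ion channels fell. H2bc18 rose by 4.30 ± 0.23 (19.6-fold), the caveolae protein gene Cavin2 by 3.52 ± 0.10, H3c4 by 3.08 ± 0.17, Depdc7 by 2.90 ± 0.14, Hexim1 by 2.76 ± 0.10 and the cytokine gene Il6 by 2.73 ± 0.12 (n = 3 per group). Gramd1c (2.70 ± 0.12), the TWEAK receptor gene Tnfrsf12a (2.65 ± 0.059), Hao1 (2.62 ± 0.18) and Slc9a3r1 (2.61 ± 0.10) rose too. The largest falls were in Nwd2 (-3.0 ± 0.20), Dleu7 (-2.84 ± 0.17) and the growth factor gene Pdgfc (-2.84 ± 0.14). Falls were also seen in the cell adhesion gene Cntn6 (-2.64 ± 0.13), Nnmt (-2.55 ± 0.12), Mal2 (-2.55 ± 0.27) and Lrrtm4, which encodes a synaptic adhesion protein (-2.55 ± 0.32). Hspb3 (-2.53 ± 0.22), Klhl14 (-2.52 ± 0.31) and Clmp (-2.40 ± 0.050) fell as well. With cyclic loess the falls of Nwd2 (-1.62), Dleu7 (-1.09), Pdgfc (-0.81), Mal2 (-0.92), Klhl14 (-1.05) and Clmp (-0.88) were smaller and still called. So were the rises of Cavin2 (1.98), Il6 (1.45), Gramd1c (1.68), Hao1 (1.37) and Slc9a3r1 (1.56), while Tnfrsf12a was at 4.18.

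Of the glutamate receptor genes, 13 of 21 measured members fell and 0 rose (13 and 0 adjusted over the list alone), among them the AMPA receptor genes Gria3 at -1.52 ± 0.14 and Gria1 at -1.36 ± 0.062, with a median of -0.52, camera adjusted p = 1.73e-05, and adjusted p = 0.00145 with an estimated correlation. Voltage-gated channel genes moved the same way: 31 of 52 fell and 3 rose (33 and 5 adjusted over the list alone), led by the potassium channels Kcnh1 at -2.38 ± 0.082 and Kcnc2 at -1.49 ± 0.088 and the sodium channel Scn2a at -1.11 ± 0.10. For voltage-gated channels, the median was -0.39, camera gave adjusted p = 1.19e-05, and adjusted p = 0.000623 with an estimated correlation. In the list of very long neuronal genes, 44 of 61 fell and 4 rose (46 and 4 adjusted over the list alone), with Cntnap5a at -1.11 ± 0.12 and Tenm2 at -1.04 ± 0.12. For very long genes, the median was -0.41, camera gave adjusted p = 4.26e-08, and adjusted p = 0.0214 with an estimated correlation. GABA genes (11 of 15 fell and 1 rose, 11 and 1 adjusted over the list alone) included the receptor gene Gabra5 at -1.95 ± 0.11. For GABA genes, camera gave adjusted p = 0.00369, and adjusted p = 0.328 with an estimated correlation. For postsynaptic proteins (22 of 39 fell and 6 rose, 22 and 6 adjusted over the list alone), camera gave adjusted p = 0.00369, and adjusted p = 0.253 with an estimated correlation. Excitatory neuron markers (13 of 22 fell and 4 rose, 13 and 4 adjusted over the list alone) included Lmo3 at -2.18 ± 0.14 and the glutamate transporter Slc17a6 at -2.05 ± 0.076. For excitatory neuron markers, camera gave adjusted p = 0.0195, and adjusted p = 0.0567 with an estimated correlation. Mitochondrial respiratory genes (39 of 91 fell and 9 rose, 39 and 10 adjusted over the list alone) had a median of -0.092. For mitochondrial genes, camera gave adjusted p = 0.00239, and adjusted p = 0.445 with an estimated correlation.

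In the other direction, 12 of 15 rose and 0 fell (12 and 0 adjusted over the list alone) of the histones, with a median of 1.17, camera adjusted p = 1.31e-07, and adjusted p = 0.0216 with an estimated correlation. Activity-induced transcription factors (19 of 32 rose and 5 fell, 19 and 5 adjusted over the list alone) included Npas4 at 1.77 ± 0.21 and Junb at 1.65 ± 0.084. For the transcription factors, camera gave adjusted p = 0.000634, and adjusted p = 0.328 with an estimated correlation. Effector genes of activity (20 of 38 rose and 5 fell, 20 and 6 adjusted over the list alone) included Gadd45b at 2.08 ± 0.087 and Nptx2 at 1.52 ± 0.086, with a median of 0.27 that turned to -0.035 with cyclic loess. For the effector genes, camera gave adjusted p = 0.000634, and adjusted p = 0.323 with an estimated correlation. Ribosomal proteins (20 of 48 rose and 2 fell, 20 and 2 adjusted over the list alone) had a median of 0.12 (camera adjusted p = 0.00239, and adjusted p = 0.323 with an estimated correlation), and heat shock genes (9 of 18 rose and 2 fell, 9 and 2 adjusted over the list alone) one of 0.18, or 0.095 without the 2 arrays that stood apart. For heat shock genes, camera gave adjusted p = 0.0379, and adjusted p = 0.328 with an estimated correlation. Cell cycle genes (20 of 46 rose and 4 fell, 20 and 4 adjusted over the list alone) had Ccne2 at 0.98 ± 0.14. For cell cycle genes, camera gave adjusted p = 0.0308, and adjusted p = 0.612 with an estimated correlation. Arc was at 0.88 ± 0.14, Egr1 at 1.14 ± 0.085, Brd2 at 1.36 ± 0.057 and Fos at 0.61 ± 0.073, while Bdnf was at 0.25 ± 0.26 (adjusted p = 0.459). With cyclic loess Arc was at 0.37 (adjusted p = 0.0486), Egr1 at 2.46 and Brd2 at 0.70. Myc fell (-0.41 ± 0.11), and with cyclic loess it rose instead (0.45, adjusted p = 0.00235).

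**Figure D2:**
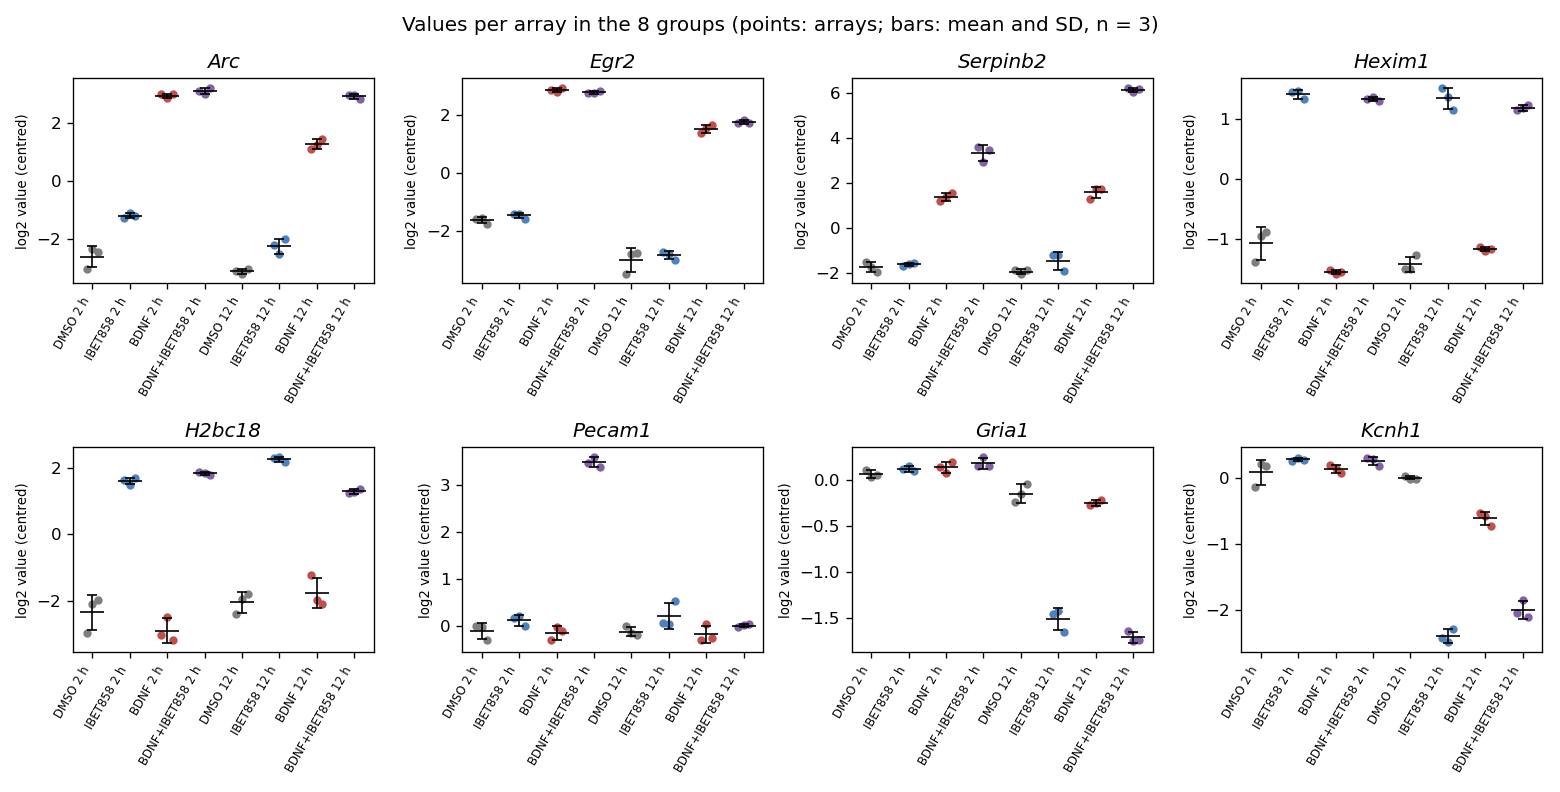
Centred log2 values of 8 genes on each of the 24 arrays by group, with bars for the mean and standard deviation (n = 3). Gria1 and Kcnh1 are low in the groups with IBET858 at 12 h, Arc and Egr2 are high in all groups with BDNF, and Pecam1 is high in BDNF+IBET858 at 2 h.

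At 12 h, 8863 genes were called, 4162 higher and 4701 lower, with 1103 and 1708 past 1.5-fold. Without IBET858 replicate 2, more genes were higher (4536) than lower (4464). Replicate 3, which stood apart, had the lowest difference between the 5-prime and 3-prime probe sets of Gapdh of all 24 arrays (-0.219, next -0.107) and, after -0.207 in DMSO at 12 h replicate 2, the lowest of beta-actin (-0.113). Without replicate 3, 3673 genes were higher and 4518 lower. The spiked-in poly-A control probe sets were higher with IBET858 at 12 h, by 0.96 without BDNF and 0.56 with it, while the hybridisation controls were higher by 0.25 and 0.22. With cyclic loess, the calls of Cntn6 (-0.0025, adjusted p = 0.992), Nnmt (-0.20, adjusted p = 0.215), glutamate receptors (median -0.24, adjusted p = 0.12), voltage-gated channels (-0.14, adjusted p = 0.0665) and all other lists named except the histones and very long genes were lost. In simulated arrays that method kept a median of 100% of a true change when levels were present, and 49.8% on values centred per gene.

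**Figure D3:**
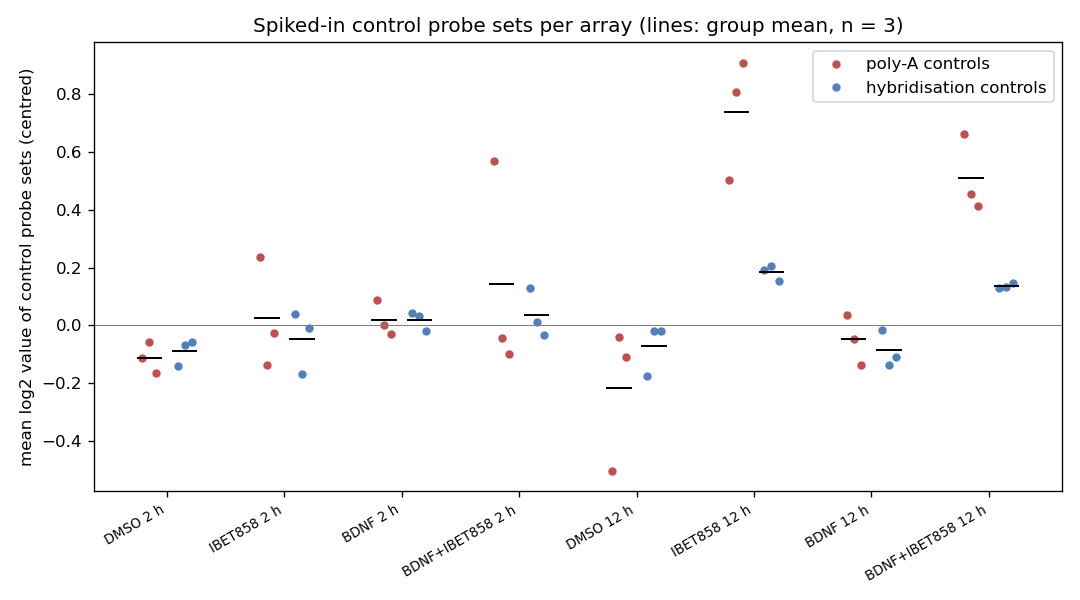
Mean centred log2 value of the poly-A controls (red, 24 probe sets) and hybridisation controls (blue, 18 probe sets) on each array, with lines at group means (n = 3). Poly-A controls average 0.74 in IBET858 and 0.51 in BDNF+IBET858 at 12 h, against -0.22 in DMSO and -0.048 in BDNF at 12 h.

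The difference between times of the IBET858 effect asks which genes respond early or late. Cavin2 was more raised at 12 h than at 2 h by 3.34 ± 0.15, Il6 by 2.71 ± 0.17, the receptor kinase gene Grk5 by 2.08 ± 0.24, Kyat3 by 1.88 ± 0.13 and Mlf1 by 1.82 ± 0.13 (n = 3 per group). The effect was lower at 12 h for Klhl14 (-3.05 ± 0.44), Rgs13 (-2.98 ± 0.67), Cntn6 (-2.72 ± 0.18), Cadps2, which acts in dense-core vesicle release (-2.62 ± 0.66), and Kcnh1 (-2.58 ± 0.12). Without DMSO at 2 h replicate 1, Rgs13 was at -1.98 and Cadps2 at -1.60, and with cyclic loess the calls of both and of Cntn6 were lost (adjusted p between 0.238 and 0.696). The others stayed called with cyclic loess at smaller values, Cavin2 at 1.97, Il6 at 1.57, Grk5 at 1.19, Kyat3 at 0.71, Mlf1 at 0.84, Klhl14 at -1.60 and Kcnh1 at -0.77.

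Of the glutamate receptor genes, 14 of 21 fell and 0 rose (15 and 0 adjusted over the list alone) in this difference, with Grik1 at -1.56 ± 0.22. For glutamate receptors, the median was -0.62, camera gave adjusted p = 3.75e-07, and adjusted p = 0.000483 with an estimated correlation. Among very long genes, 36 of 61 fell and 2 rose (40 and 3 adjusted over the list alone), with Kcnma1 at -1.26 ± 0.14. For very long genes, the median was -0.38, camera gave adjusted p = 6.99e-08, and adjusted p = 0.0237 with an estimated correlation. For voltage-gated channels, 23 of 52 fell and 6 rose (24 and 7 adjusted over the list alone), a call lost with cyclic loess (adjusted p = 0.11). Their median was -0.20, camera gave adjusted p = 0.000144, and adjusted p = 0.00124 with an estimated correlation. Without the 2 arrays that stood apart that median was -0.30. With cyclic loess the median was -0.17 for glutamate receptors and -0.19 for very long genes, both still called. GABA genes had a median of -0.60 (camera adjusted p = 5.96e-05, and adjusted p = 0.161 with an estimated correlation), presynaptic genes -0.18 (camera adjusted p = 0.0132, and adjusted p = 0.0971 with an estimated correlation), and axon guidance genes -0.23 (camera adjusted p = 0.0188, and adjusted p = 0.241 with an estimated correlation). In total 6030 genes were called, 2871 higher and 3159 lower, and with cyclic loess 2188 were higher and 1964 lower. Brd2 was higher by 0.65 ± 0.081, a call lost with cyclic loess (0.067, adjusted p = 0.649). Egr1 was at -0.19 ± 0.12 (adjusted p = 0.275) but rose with cyclic loess (1.12).

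BDNF against DMSO at 2 h shows the early response of these neurons to the growth factor. Every activity-induced transcription factor on the list rose. Arc, which regulates AMPA receptor traffic, rose by 5.59 ± 0.14 (48.2-fold), the transcription factor Egr2 by 4.50 ± 0.13, Btg2 by 4.25 ± 0.14, Rrad by 4.04 ± 0.11 and the kinase gene Pim1 by 3.71 ± 0.085 (n = 3 per group). Gadd45b (3.22 ± 0.087), Tnfrsf12a (3.19 ± 0.059), the protease inhibitor gene Serpinb2 (3.09 ± 0.17), Gadd45g (2.98 ± 0.20) and the chemokine receptor gene Cxcr4 (2.95 ± 0.16) followed. Falls were smaller. Ttc30b (-1.93 ± 0.11), Zkscan4 (-1.87 ± 0.085), Zbed5 (-1.76 ± 0.076), Nr0b1 (-1.70 ± 0.22) and Kctd4 (-1.69 ± 0.37, and -0.93 without DMSO replicate 1) fell. So did Zfp58 (-1.61 ± 0.15), Zc3hav1l (-1.60 ± 0.082), Zfp647 (-1.60 ± 0.071), Pnma1 (-1.55 ± 0.077) and Zfp867 (-1.54 ± 0.10).

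For activity-induced transcription factors, 32 of 32 measured members rose and 0 fell (32 and 0 adjusted over the list alone), with a median of 1.61, camera adjusted p = 1.12e-44, and adjusted p = 0.000262 with an estimated correlation. Egr1 rose by 2.61 ± 0.085 and Fos by 0.75 ± 0.073. Among effector genes of activity, 33 of 38 rose and 0 fell (36 and 0 adjusted over the list alone). For the effector genes, the median was 1.32, camera gave adjusted p = 1.22e-42, and adjusted p = 0.000142 with an estimated correlation. Bdnf rose by 1.18 ± 0.26, and by 0.65 without DMSO replicate 1. MAP kinase feedback regulators (16 of 24 rose and 1 fell, 16 and 1 adjusted over the list alone) included the phosphatase genes Dusp1 at 2.23 ± 0.21 and Dusp4 at 2.12 ± 0.16. For MAP kinase feedback regulators, the median was 0.80, camera gave adjusted p = 4.81e-12, and adjusted p = 0.0392 with an estimated correlation. NF-kappaB and inflammatory genes (9 of 31 rose and 1 fell, 12 and 1 adjusted over the list alone) included Ptgs2 at 1.86 ± 0.22. For NF-kappaB genes, the median was 0.10, camera gave adjusted p = 0.00131, and adjusted p = 0.0392 with an estimated correlation. In the p53 list (9 of 28 rose and 4 fell, 10 and 5 adjusted over the list alone), the largest rises were Btg2 and Tnfrsf12a, which also stand in the activity lists, and the cell cycle inhibitor Cdkn1a at 1.77 ± 0.069. For p53 targets, the median was 0.058, camera gave adjusted p = 0.00454, and adjusted p = 0.0261 with an estimated correlation, and the median was below 0 when the most variable probe set stood for each gene.

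Neuropeptide genes (17 of 26 rose and 0 fell, 17 and 0 adjusted over the list alone) included Vgf at 2.23 ± 0.26 and Nts at 1.77 ± 0.25. For neuropeptides, camera gave adjusted p = 2.9e-08, and adjusted p = 0.136 with an estimated correlation. Endoplasmic reticulum stress genes (12 of 35 rose and 0 fell, 12 and 0 adjusted over the list alone) had a median of 0.16 (camera adjusted p = 0.000668, and adjusted p = 0.476 with an estimated correlation), and heat shock genes (8 of 18 rose and 2 fell, 8 and 2 adjusted over the list alone) had Dnajb1 at 2.09 ± 0.056. For heat shock genes, camera gave adjusted p = 0.0021, and adjusted p = 0.136 with an estimated correlation. Interneuron markers (7 of 22 rose and 0 fell, 8 and 0 adjusted over the list alone; camera adjusted p = 0.00357, and adjusted p = 0.596 with an estimated correlation) lost their call without the 2 arrays that stood apart (adjusted p = 0.0917). In that fit the median of neuropeptides went from 0.44 to 0.24 and that of endoplasmic reticulum stress genes from 0.16 to 0.062. Hexim1 fell (-0.48 ± 0.10). In all, 5068 genes were called, 1781 higher and 3287 lower, with 467 and 569 past 1.5-fold, and with array weights 7941 were called, 3185 higher and 4756 lower. The rise of Myc (0.33 ± 0.11) was lost without DMSO replicate 1 (0.14, adjusted p = 0.197) and without BDNF replicate 2 (0.32, adjusted p = 0.0686) or replicate 3 (0.31, adjusted p = 0.081).

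BDNF against DMSO at 12 h shows the later response. The small GTPase gene Rasl11a rose by 4.90 ± 0.10 (29.8-fold), Egr2 by 4.54 ± 0.13, Arc by 4.42 ± 0.14, the neurofilament gene Nefm by 3.94 ± 0.10 and the acetylcholine receptor gene Chrna1 by 3.79 ± 0.13 (n = 3 per group). Nrn1, which encodes neuritin, rose by 3.68 ± 0.087, Serpinb2 by 3.51 ± 0.17, the metalloprotease gene Adamts1 by 3.47 ± 0.16, Nptx1 by 3.46 ± 0.093 and Man1a by 3.28 ± 0.076. Arhgef26 (-2.32 ± 0.094), Smim17 (-2.27 ± 0.12), Ssbp2 (-2.11 ± 0.13), Armh4 (-2.05 ± 0.077) and Glis3 (-1.99 ± 0.21) fell. So did the connexin gene Gjc1 (-1.96 ± 0.10), Myh3 (-1.93 ± 0.28), Lemd1 (-1.92 ± 0.28), Pik3ip1 (-1.91 ± 0.11) and Creg2 (-1.89 ± 0.085). Smaller falls came with cyclic loess for Glis3 (-0.97), Lemd1 (-0.84) and Creg2 (-1.25), all still called.

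Both activity lists stayed up. Of the transcription factors, 29 of 32 rose and 0 fell (29 and 0 adjusted over the list alone). Their median was 1.01, camera gave adjusted p = 4e-20, and adjusted p = 0.0158 with an estimated correlation. Of the effector genes, 34 of 38 rose and 1 fell (34 and 2 adjusted over the list alone). For the effector genes, the median was 1.10, camera gave adjusted p = 1.29e-23, and adjusted p = 0.00383 with an estimated correlation. MAP kinase feedback regulators (16 of 24 rose and 2 fell, 17 and 2 adjusted over the list alone) included Dusp4 at 2.44 ± 0.16 and Spry2 at 2.17 ± 0.18. For MAP kinase feedback regulators, camera gave adjusted p = 2.17e-08, and adjusted p = 0.174 with an estimated correlation. Neuropeptide genes (16 of 26 rose and 4 fell, 16 and 4 adjusted over the list alone) included Nts at 2.52 ± 0.25 and Igf1 at 2.10 ± 0.13. For neuropeptides, camera gave adjusted p = 5.1e-05, and adjusted p = 0.467 with an estimated correlation. Stress genes of the endoplasmic reticulum passed camera upward (17 of 35 rose and 4 fell, 19 and 4 adjusted over the list alone; camera adjusted p = 0.000373, and adjusted p = 0.526 with an estimated correlation). Ribosomal proteins did so too (18 of 48 rose and 1 fell, 18 and 1 adjusted over the list alone; camera adjusted p = 0.0127, and adjusted p = 0.526 with an estimated correlation). Mitochondrial respiratory genes passed it downward (36 of 91 fell and 4 rose, 36 and 4 adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.687 with an estimated correlation), a call lost with cyclic loess (adjusted p = 0.238). In all, 7463 genes were called, 3067 higher and 4396 lower, with 830 and 1126 past 1.5-fold. Egr1 rose by 3.06 ± 0.085, Fos by 0.72 ± 0.073, Myc by 0.49 ± 0.11 and Bdnf by 0.84 ± 0.26, the last not without DMSO replicate 1 (0.66, adjusted p = 0.0811).

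The difference between times of the BDNF effect sets the response over DMSO at 12 h against that at 2 h. It also moves with the DMSO groups. For Egr2, DMSO arrays lay between -1.75 and -1.54 at 2 h and between -3.48 and -2.76 at 12 h. BDNF arrays lay between 2.81 and 2.95 and between 1.38 and 1.66, so the effect was 4.50 and 4.54. Chrna1 was more raised at 12 h by 3.87 ± 0.19, Man1a by 3.34 ± 0.11, Gask1b by 2.74 ± 0.19, the lipid kinase gene Dgkk by 2.69 ± 0.13 and Cyp26b1, which degrades retinoic acid, by 2.67 ± 0.20 (n = 3 per group). The effect was smaller or lower at 12 h for Lemd1 (-2.29 ± 0.39), Myh3 (-2.26 ± 0.39), Gadd45b (-2.21 ± 0.12), the phosphatase gene Dusp14 (-2.14 ± 0.12) and the chaperone gene Dnajb1 (-2.12 ± 0.079). Activity-induced transcription factors were lower in this difference (18 of 32 fell and 2 rose, 19 and 3 adjusted over the list alone), with a median of -0.52, camera adjusted p = 1.35e-05, and adjusted p = 0.547 with an estimated correlation. Arc was lower (-1.17 ± 0.19) and Egr1 higher by 0.45 ± 0.12. With cyclic loess Lemd1 was at -1.47 and Egr1 at 0.72. In all, 4518 genes were called, 2349 higher and 2169 lower.

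BDNF with IBET858 against BDNF at 2 h asks what the inhibitor changes in the early response to BDNF. H2bc18 was higher by 4.72 ± 0.23 (26.4-fold), Rcc1, the exchange factor of Ran, by 3.71 ± 0.071, Caprin2 by 3.67 ± 0.084, the adhesion molecule gene Pecam1 by 3.64 ± 0.12, Depdc7 by 3.56 ± 0.14 and Fam83d by 3.44 ± 0.10 (n = 3 per group). H3c4 (3.43 ± 0.17), Ckmt2 (3.35 ± 0.12), Polg2, a subunit of the mitochondrial DNA polymerase (3.29 ± 0.089), and Hexim1 (2.88 ± 0.10) were higher too. Cxcr4 (-2.91 ± 0.16), Tmem74 (-2.68 ± 0.10), the EGR corepressor gene Nab2 (-2.50 ± 0.14), Tent5a (-2.49 ± 0.20) and Rrad (-2.36 ± 0.11) were lower. So were the potassium channel genes Kcnf1 (-2.42 ± 0.064) and Kcns2 (-1.91 ± 0.088), Mir124a-1hg (-2.36 ± 0.083), Ccsap (-2.16 ± 0.10) and Rbm24 (-2.01 ± 0.069). Bdnf was lower (-1.37 ± 0.26), whereas Arc was at 0.17 ± 0.14 (adjusted p = 0.383) and Egr1 at 0.10 ± 0.085 (adjusted p = 0.398).

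Histones (11 of 15 rose and 0 fell, 13 and 0 adjusted over the list alone) had a median of 0.90, camera adjusted p = 1.33e-11, and adjusted p = 0.0126 with an estimated correlation, and heat shock genes (11 of 18 rose and 1 fell, 11 and 2 adjusted over the list alone), with Hspa1b at 2.78 ± 0.12, a median of 0.29, camera adjusted p = 8.02e-06, and adjusted p = 0.0488 with an estimated correlation. Activity-induced transcription factors went both ways (14 of 32 rose and 9 fell, 14 and 10 adjusted over the list alone), with Klf2 at 1.79 ± 0.080 and Klf10 at -1.26 ± 0.17 (camera adjusted p = 0.715). So did effector genes of activity (11 of 38 rose and 10 fell, 14 and 12 adjusted over the list alone), with Plk3 at 1.69 ± 0.087 and Rasl11a at -1.59 ± 0.10 (camera adjusted p = 0.72). Cell cycle genes (12 of 46 rose and 0 fell, 12 and 0 adjusted over the list alone; camera adjusted p = 0.0406, and adjusted p = 0.856 with an estimated correlation) included Ccne2 at 1.69 ± 0.14. Autism-associated genes (18 of 66 fell and 4 rose, 20 and 7 adjusted over the list alone; camera adjusted p = 0.0406, and adjusted p = 0.728 with an estimated correlation) included Dyrk1a at -0.86 ± 0.12. Interferon response genes (5 of 34 rose and 0 fell, 5 and 0 adjusted over the list alone; camera adjusted p = 0.0406, and adjusted p = 0.728 with an estimated correlation) included Irf1 at 1.25 ± 0.10. Vascular markers (7 of 29 rose and 1 fell, 7 and 1 adjusted over the list alone; camera adjusted p = 0.0406, and adjusted p = 0.856 with an estimated correlation) included Pecam1 and Slc2a1 at 1.42 ± 0.080. In all, 4928 genes were called, 2212 higher and 2716 lower. The last 4 of these lists lost their calls when the most variable probe set stood for each gene (adjusted p between 0.094 and 0.105). With cyclic loess the median was 0.051 for cell cycle genes and -0.072 for autism-associated genes, both still called.

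BDNF with IBET858 against BDNF at 12 h asks the same of the later response. Serpinb2 was higher by 4.53 ± 0.17 (23-fold), Cavin2 by 3.48 ± 0.10, Depdc7 by 3.21 ± 0.14, Grk5 by 3.13 ± 0.17, H2bc18 by 3.05 ± 0.23 and the imprinted gene Peg10 by 3.0 ± 0.28 (n = 3 per group). Slc9a3r1 (2.94 ± 0.10), Pim1 (2.83 ± 0.085, not called with cyclic loess at 0.50), Mreg (2.81 ± 0.18) and Gxylt2 (2.80 ± 0.12) were higher too. Gask1b (-3.94 ± 0.14), Tcim (-3.88 ± 0.24), Rgs13 (-3.82 ± 0.47), Cthrc1 (-3.59 ± 0.20) and Chrna1 (-3.23 ± 0.13) were lower. So were Dleu7 (-3.15 ± 0.17), the epilepsy gene Lgi1 (-3.05 ± 0.11), the caveolin gene Cav1 (-3.01 ± 0.19), Pcdh20 (-3.0 ± 0.22) and Stum (-2.99 ± 0.16). With cyclic loess Serpinb2 (2.09), Cavin2 (1.05), Grk5 (1.66), Slc9a3r1 (1.44), Gxylt2 (1.12), Rgs13 (-2.08), Dleu7 (-1.56) and Lgi1 (-1.68) kept their calls at smaller values, and Chrna1 was at -5.18.

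As without BDNF, glutamate receptors were lower (14 of 21 fell and 0 rose, 14 and 0 adjusted over the list alone), with Gria3 at -2.81 ± 0.14 and Grm5 at -1.42 ± 0.093. For glutamate receptors, the median was -0.52, camera gave adjusted p = 0.000174, and adjusted p = 0.00431 with an estimated correlation. Voltage-gated channels were lower as well (32 of 52 fell and 6 rose, 34 and 7 adjusted over the list alone), with Kcnc2 at -2.03 ± 0.088 and Scn2a at -1.77 ± 0.10. For voltage-gated channels, the median was -0.31, camera gave adjusted p = 0.000118, and adjusted p = 0.00192 with an estimated correlation. Very long genes (35 of 61 fell and 9 rose, 35 and 9 adjusted over the list alone) had a median of -0.35, camera adjusted p = 0.000201, and adjusted p = 0.144 with an estimated correlation. GABA genes passed camera downward, and 9 of 15 fell and 1 rose (9 and 1 adjusted over the list alone). There, camera adjusted p = 0.00261, and adjusted p = 0.335 with an estimated correlation. Among postsynaptic proteins, 21 of 39 fell and 8 rose (21 and 8 adjusted over the list alone). Here camera adjusted p = 0.0293, and adjusted p = 0.335 with an estimated correlation. Of the excitatory neuron markers, 12 of 22 fell and 3 rose (12 and 3 adjusted over the list alone), with camera adjusted p = 0.0416, and adjusted p = 0.138 with an estimated correlation. Of the mitochondrial respiratory genes, 41 of 91 fell and 6 rose (42 and 6 adjusted over the list alone), with camera adjusted p = 0.00263, and adjusted p = 0.567 with an estimated correlation.

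Other lists went up at 12 h. Of the histones, 12 of 15 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 1.21, camera gave adjusted p = 1.02e-05, and adjusted p = 0.0674 with an estimated correlation. Of the cell cycle genes, 26 of 46 rose and 0 fell (27 and 0 adjusted over the list alone), with camera adjusted p = 6.83e-05, and adjusted p = 0.335 with an estimated correlation. Of the heat shock genes, 12 of 18 rose and 2 fell (12 and 2 adjusted over the list alone), with camera adjusted p = 0.00261, and adjusted p = 0.166 with an estimated correlation. Activity-induced transcription factors were mostly higher, as 18 of 32 rose and 7 fell (18 and 7 adjusted over the list alone). For these factors, camera gave adjusted p = 0.0361, and adjusted p = 0.663 with an estimated correlation. Of the effector genes, 21 of 38 rose and 12 fell (21 and 12 adjusted over the list alone), with camera adjusted p = 0.0019, and adjusted p = 0.335 with an estimated correlation. Arc was higher by 1.66 ± 0.14 and Bdnf lower (-0.70 ± 0.26), the latter call being lost whenever 1 array of BDNF or BDNF+IBET858 at 12 h was left out (adjusted p between 0.0514 and 0.0928). In these fits, which have fewer samples, Bdnf was between -0.74 and -0.64.

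At 12 h, 8511 genes were called in this comparison, 3848 higher and 4663 lower, and with cyclic loess 3923 were higher and 3750 lower. With cyclic loess the histones (median 0.51), cell cycle genes (0.16) and voltage-gated channels (-0.19) kept their calls at smaller medians, and Arc was at 0.99. The other 9 lists did not keep theirs, among them glutamate receptors (median -0.13, adjusted p = 0.077) and very long genes (-0.12, adjusted p = 0.0572).

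**Figure D4:**
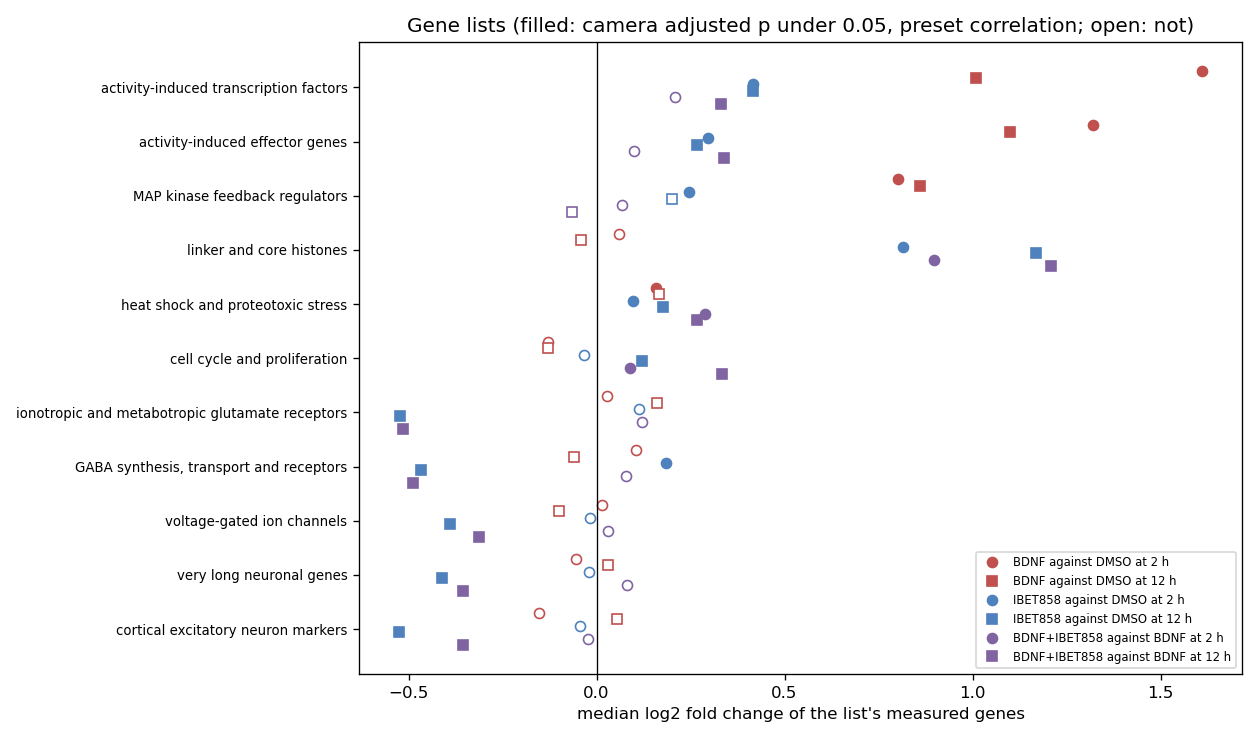
Median log2 fold change of the measured members of 11 gene lists in 6 comparisons, filled where camera passed an adjusted p of 0.05 with the preset correlation. Activity-induced lists lie highest with BDNF alone, and channel and receptor lists lie below 0 with IBET858 at 12 h.

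BDNF with IBET858 against IBET858 at 2 h asks how far neurons under the inhibitor still respond to BDNF. Serpinb2 rose by 4.92 ± 0.17 (30.3-fold), Arc by 4.34 ± 0.14, Egr2 by 4.26 ± 0.13, Caprin2 by 3.53 ± 0.084 and Pecam1 by 3.37 ± 0.12 (n = 3 per group). Tbr1, a transcription factor of deep cortical layers (-1.45 ± 0.14), Ttc30b (-1.44 ± 0.11), Zkscan4 (-1.28 ± 0.085), Mkrn3 (-1.27 ± 0.058) and Tgds (-1.18 ± 0.080) fell. Of the activity-induced transcription factors, 30 of 32 rose and 0 fell (30 and 0 adjusted over the list alone). Their median was 1.17, camera gave adjusted p = 3.35e-42, and adjusted p = 0.000362 with an estimated correlation. Of the effector genes, 27 of 38 rose and 0 fell (29 and 0 adjusted over the list alone). For the effector genes, the median was 0.90, camera gave adjusted p = 2.03e-37, and adjusted p = 0.000314 with an estimated correlation. Of the heat shock genes, 10 of 18 rose and 0 fell (11 and 2 adjusted over the list alone), with camera adjusted p = 9.13e-10, and adjusted p = 0.00383 with an estimated correlation. Of the NF-kappaB genes, 7 of 31 rose and 1 fell (7 and 1 adjusted over the list alone), with Ptgs2 at 0.94 ± 0.22. For this list, camera gave adjusted p = 0.000449, and adjusted p = 0.0275 with an estimated correlation. Of the p53 targets, 8 of 28 rose and 4 fell (8 and 4 adjusted over the list alone), with Btg2 at 3.32 ± 0.14. For that list, camera gave adjusted p = 0.00321, and adjusted p = 0.0146 with an estimated correlation. In all, 3850 genes were called, 1172 higher and 2678 lower. Camera passed 11 other lists, which lost their calls with an estimated correlation, at adjusted p between 0.0788 and 0.482.

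BDNF with IBET858 against IBET858 at 12 h gives the later response under the inhibitor. Serpinb2 rose by 7.56 ± 0.17, the matrix gene Tnc by 5.78 ± 0.19, Arc by 5.20 ± 0.14, Egr2 by 4.60 ± 0.13 and the antioxidant enzyme gene Srxn1 by 3.98 ± 0.067 (n = 3 per group). The Eph receptor gene Ephb6 (-2.23 ± 0.088), Il6 (-2.13 ± 0.12), Pnma1 (-1.91 ± 0.077), Gucy1a1 (-1.84 ± 0.079) and Sybu (-1.81 ± 0.092) fell. Of the activity-induced transcription factors, 28 of 32 rose and 1 fell (28 and 1 adjusted over the list alone). Their median was 0.97, camera gave adjusted p = 7.15e-20, and adjusted p = 0.0166 with an estimated correlation. Of the effector genes, 31 of 38 rose and 2 fell (32 and 2 adjusted over the list alone). Their median was 1.26, camera gave adjusted p = 6.67e-27, and adjusted p = 0.00193 with an estimated correlation. MAP kinase feedback regulators (18 of 24 rose and 1 fell, 19 and 1 adjusted over the list alone) included Dusp6 at 2.44 ± 0.082. For MAP kinase feedback regulators, camera gave adjusted p = 2.69e-10, and adjusted p = 0.0696 with an estimated correlation. Histones were lower (9 of 15 fell and 0 rose, 9 and 0 adjusted over the list alone; camera adjusted p = 0.009, and adjusted p = 0.35 with an estimated correlation). Progenitor markers (7 of 19 rose and 0 fell, 7 and 0 adjusted over the list alone; camera adjusted p = 0.00778, and adjusted p = 0.138 with an estimated correlation) were led by Tnc and the intermediate filament gene Vim (2.86 ± 0.075). Camera also passed the lists of neuropeptides, cholesterol, very long genes, mitochondrial genes, heat shock and p53 targets, with adjusted p between 0.0613 and 0.574 under an estimated correlation. Without the 2 arrays that stood apart, very long genes lost their call (adjusted p = 0.152), and the median of p53 targets went from 0.076 to 0.012 and that of progenitor markers from 0.032 to 0.058. With cyclic loess these medians were 0.15 and 0.14, that of activity-induced transcription factors was 0.64, that of very long genes went from 0.080 to 0.15, and mitochondrial genes lost their call (adjusted p = 0.424). In all, 7150 genes were called, 2923 higher and 4227 lower, and with cyclic loess 3352 were higher and 3271 lower. Brd2 was at 0.10 ± 0.057 (adjusted p = 0.179) and fell with cyclic loess (-0.29).

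The interaction at 2 h asks whether the inhibitor changes the response to BDNF itself. Positive values mean a higher log2 value with both treatments than their separate log2 effects add up to. On this scale, adding effects means multiplying fold changes, not adding amounts of RNA. Pecam1 (3.41 ± 0.17), Rcc1 (2.76 ± 0.10), Tmem54 (2.68 ± 0.22), Caprin2 (2.66 ± 0.12) and Zmym1 (2.15 ± 0.12) were highest (n = 3 per group). Rrad (-2.42 ± 0.15), Ier5l (-2.38 ± 0.12), Cxcr4 (-2.04 ± 0.23), Tmem74 (-1.95 ± 0.14) and Rasl11a (-1.92 ± 0.14) were lowest. Arc was at -1.25 ± 0.19 and Egr1 at -1.22 ± 0.12, while Fos was at -0.02 ± 0.10 (adjusted p = 0.945) and Bdnf at -0.99 ± 0.37 (adjusted p = 0.117). Without BDNF, IBET858 raised Arc by 1.42 and Egr1 by 1.33. Added to BDNF, it left Arc at 0.17 (adjusted p = 0.383) and Egr1 at 0.10 (adjusted p = 0.398). Their negative interactions thus reflect the rise with IBET858 alone, not a lower level with both treatments. Activity-induced transcription factors were lower (13 of 32 fell and 0 rose, 14 and 2 adjusted over the list alone), with Klf10 at -1.45 ± 0.24. For the transcription factors, the median was -0.29, camera gave adjusted p = 2.89e-09, and adjusted p = 0.154 with an estimated correlation. Effector genes of activity were lower too (13 of 38 fell and 5 rose, 22 and 6 adjusted over the list alone), with a median of -0.42, camera adjusted p = 9.74e-08, and adjusted p = 0.154 with an estimated correlation. MAP kinase feedback regulators (8 of 24 fell and 1 rose, 12 and 2 adjusted over the list alone) had Spry2 at -1.18 ± 0.26 and Spry1 at 1.27 ± 0.11. For MAP kinase feedback regulators, camera gave adjusted p = 0.000196, and adjusted p = 0.421 with an estimated correlation. Without the 2 arrays that stood apart, the median of effector genes was -0.26 and that of MAP kinase feedback regulators went from -0.30 to -0.16. Heat shock genes (6 of 18 rose and 0 fell, 7 and 0 adjusted over the list alone) had the small chaperone gene Hspb8 at 1.29 ± 0.17. For heat shock genes, camera gave adjusted p = 0.000196, and adjusted p = 0.154 with an estimated correlation. In all, 1529 genes were called, 566 higher and 963 lower, and with array weights 2732, of which 1199 were higher and 1533 lower.

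The interaction at 12 h asks the same of the later response. It was highest for Serpinb2 (4.04 ± 0.25), Tnc (3.54 ± 0.27), the cytokine subunit gene Ebi3 (3.09 ± 0.17), Gxylt2 (2.73 ± 0.18) and Slc17a6 (2.19 ± 0.11). It was lowest for Chrna1 (-3.12 ± 0.19), Cyp26b1 (-3.11 ± 0.20), Cthrc1 (-2.90 ± 0.28), Gask1b (-2.57 ± 0.19) and the metallothionein gene Mt2 (-2.39 ± 0.13; n = 3 per group). Arc was positive at 0.78 ± 0.19 and Egr1 negative at -0.80 ± 0.12. IBET858 raised Egr1 by 1.14 without BDNF and by 0.34 with it. Activity-induced transcription factors went both ways (11 of 32 fell and 4 rose, 13 and 4 adjusted over the list alone), with camera adjusted p = 0.079. Of the ribosomal proteins, 9 of 48 fell and 0 rose (9 and 0 adjusted over the list alone), with camera adjusted p = 0.000594, and adjusted p = 0.854 with an estimated correlation. Of the neuropeptides, 7 of 26 fell and 2 rose (8 and 2 adjusted over the list alone), with camera adjusted p = 0.0377, and adjusted p = 0.854 with an estimated correlation. Of the endoplasmic reticulum stress genes, 8 of 35 fell and 2 rose (9 and 2 adjusted over the list alone). For this group, camera gave adjusted p = 0.019, and adjusted p = 0.854 with an estimated correlation. Cell cycle genes passed it upward (8 of 46 rose and 2 fell, 8 and 2 adjusted over the list alone; camera adjusted p = 0.0347, and adjusted p = 0.854 with an estimated correlation). With cyclic loess the median of ribosomal proteins was -0.076. In all, 2945 genes were called, 1627 higher and 1318 lower.

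The effects of IBET858 with and without BDNF share no array and can be set side by side. At 2 h their log2 fold changes correlated across genes at r = 0.663, with 708 genes higher in both against 125 if the calls were independent, 1214 lower in both against 252, and 44 in opposite directions against 358. At 12 h, r was 0.798, with 2758 higher in both against 880, 3540 lower in both against 1200, and 191 opposite against 2060. Hexim1, H2bc18 and Depdc7 were called higher and Mir124a-1hg lower in both comparisons at 2 h. For BDNF with and without IBET858, r was 0.647 at 2 h and 0.695 at 12 h, and 533 and 1863 genes were higher in both.

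Of the 1781 genes raised by BDNF at 2 h, 880 (49.4%) were lower with BDNF and IBET858 than with BDNF alone, and 239 (13.4%) were higher. Cxcr4, Rrad, Rasl11a and Bdnf were among the lower genes and Serpinb2 among the higher. Independent calls would give 266 lower genes, but both comparisons use the same BDNF arrays, which ties their calls. A negative interaction was called for 664 of the 1781 (37.3%). The interaction contains the BDNF effect with reversed sign, on the same BDNF and DMSO arrays. Choosing genes raised by BDNF thus pushes it down through noise, so this count is tied too. At 12 h, 1344 of 3067 raised genes (43.8%) were lower with the inhibitor, among them Chrna1, Rasl11a and Nptx1, and 848 (27.6%) were higher, among them Arc and Serpinb2. Independent calls would give 786, and the interaction was negative for 747 (24.4%), with the same ties in both counts. Even so, 1863 of the 3067 (60.7%) were also called higher than with IBET858 alone at 12 h, against 533 of 1781 (29.9%) at 2 h. Genes with a rise too small to be called count as not raised, so these shares depend on the threshold. Of the genes raised over 2-fold by BDNF, 147 of 205 were also called higher than with IBET858 alone at 2 h and 277 of 324 at 12 h.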

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

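The tests chosen only after the result was seen are the 3 on the poly-A controls, those on an odd array and on endothelial cells, and the 4 that shuffled residuals. The neighbour test and the splits of the samples were set beforehand. All results of the next 4 comparisons stand here because the effect of 1 treatment differed between groups, by the test of the difference itself (n = 3 per group).

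The inhibitor changed the response to BDNF at 2 h for 1529 genes. Pecam1 (3.41 ± 0.17), Rcc1 (2.76 ± 0.10), Tmem54 (2.68 ± 0.22), Caprin2 (2.66 ± 0.12) and Zmym1 (2.15 ± 0.12) were higher than the 2 log2 effects add up to. Rrad (-2.42 ± 0.15), Ier5l (-2.38 ± 0.12), Cxcr4 (-2.04 ± 0.23), Tmem74 (-1.95 ± 0.14) and Rasl11a (-1.92 ± 0.14) were lower. Activity-induced transcription factors (median -0.29), effector genes (-0.42), MAP kinase feedback regulators (-0.30) and autism-associated genes (-0.063) passed camera downward. Among the called members of both activity lists, most rose with IBET858 alone at 2 h, and they went both ways when it was added to BDNF. Without DMSO at 2 h replicate 1 and IBET858 at 12 h replicate 3, the effector median was -0.26 and that of MAP kinase feedback regulators -0.16. Histones (0.26), heat shock genes (0.18) and endothelial, mural and fibroblast markers (0.12) passed it upward. With an estimated correlation, all of these lists lost their calls, with adjusted p between 0.154 and 0.589. The other 5 lists passed camera but lost their calls in that fit. They were GABA genes (-0.19, adjusted p = 0.345 without the 2 arrays), BET and elongation factors (-0.15, adjusted p = 0.118), cell cycle genes (0.14, adjusted p = 0.0592), interneuron markers (-0.23, adjusted p = 0.324) and clock genes (-0.20, adjusted p = 0.118). Their adjusted p with an estimated correlation lay between 0.45 and 0.595.

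Of the 100 splits of the 12 arrays at 2 h into groups of the same sizes, 11 called as many genes, and the highest other called 4711, so this test does not exclude chance. Regroupings bring the effects of the treatments themselves into the contrast, so counts several times the real one point to this structure of the samples. When the additive effects were removed and the residuals shuffled, 1 of 100 arrangements, the real one, gave as many genes. The highest other gave 206.

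The genes raised beyond the added log2 effects at 2 h form a pattern of their own. An odd array among the BDNF+IBET858 replicates is argued against, since 507, 516 and 455 genes were still called higher without each in turn. At most 0.394% of the genes called higher without an array lay at or below 0 on that array (0.388% and 0.22% for the others). The arrays of the other groups enter both these calls and these readings, which pushes the shares down. Endothelial cells are argued against too, since the other 6 endothelial markers had a median of 0.081 beside Pecam1 at 3.41. A candidate explanation is transcription running on from a neighbouring gene, since 14.5% of these genes (82 of 566) had a raised neighbour, against a mean of 6.11% and a highest of 11.5% in 10000 random sets. Pairs, picked after their values were seen, include Ipo8 with Caprin2 (1.68 and 2.66), Rnf19b with Tmem54 (0.99 and 2.68) and Trnau1ap with Rcc1 (0.75 and 2.76). Other pairs are related genes, which a probe set may read together, such as Hspa1b with Hspa1a (0.927 and 0.816) and H3c7 with H3c4 (0.824 and 0.995). The test used the order of genes and not their strand, so it cannot tell running on from other clustering of raised genes. The excess over random sets was 2.37-fold here and between 1.08-fold and 1.65-fold in the other sets of higher or lower genes. This set was the smallest, and the random share was 6.11% here and between 10.3% and 45% in the others. A small random share leaves room for a larger ratio, so the ratios are not on equal terms. The genes lower in the same interaction, with a random share of 10.3%, had 1.31-fold. Shared regulation of neighbours stays open, and a change by the treatments themselves was not separated from either.

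At 12 h the response to BDNF differed with the inhibitor for 2945 genes. Serpinb2 (4.04 ± 0.25), Tnc (3.54 ± 0.27), Ebi3 (3.09 ± 0.17), Gxylt2 (2.73 ± 0.18) and Slc17a6 (2.19 ± 0.11) were higher. Chrna1 (-3.12 ± 0.19), Cyp26b1 (-3.11 ± 0.20), Cthrc1 (-2.90 ± 0.28), Gask1b (-2.57 ± 0.19) and Mt2 (-2.39 ± 0.13) were lower. Neuropeptides (-0.21), ribosomal proteins (-0.13) and endoplasmic reticulum stress genes (-0.22) passed camera downward and cell cycle genes (0.13) upward, each with adjusted p = 0.854 under an estimated correlation. As many genes came from 12 of 100 splits, with 8035 in the highest other, so chance is not excluded by this test, and the structure of the samples again shows in it. Shuffled residuals gave as many in 1 of 100, the real one, with 1339 in the highest other.

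The IBET858 effect differed between 12 h and 2 h for 6030 genes. Cavin2 (3.34 ± 0.15), Il6 (2.71 ± 0.17), Grk5 (2.08 ± 0.24), Kyat3 (1.88 ± 0.13) and Mlf1 (1.82 ± 0.13) were higher at 12 h. Klhl14 (-3.05 ± 0.44), Rgs13 (-2.98 ± 0.67), Cntn6 (-2.72 ± 0.18), Cadps2 (-2.62 ± 0.66) and Kcnh1 (-2.58 ± 0.12) were lower. Without DMSO at 2 h replicate 1, Rgs13 was at -1.98 and Cadps2 at -1.60. Glutamate receptors (-0.62), voltage-gated channels (-0.20) and very long genes (-0.38) kept their calls with an estimated correlation, at adjusted p between 0.000483 and 0.0237. With cyclic loess glutamate receptors were at -0.17 and very long genes at -0.19, and voltage-gated channels lost their call (adjusted p = 0.11). Postsynaptic (-0.24), presynaptic (-0.18), GABA (-0.60), axon guidance (-0.23) and mitochondrial genes (-0.12), cell cycle genes (0.15), excitatory neuron markers (-0.28) and microglia markers (-0.22) lost theirs, at adjusted p between 0.0971 and 0.574. Of 100 splits, 1, the real one, gave as many genes, with 3716 in the highest other. These regroupings also bring the effects of treatment and time into the contrast, so by themselves they do not exclude chance. Shuffled residuals gave 1 of 100, the real one, with 3281 in the highest other.

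The BDNF effect differed between the times for 4518 genes. Chrna1 (3.87 ± 0.19), Man1a (3.34 ± 0.11), Gask1b (2.74 ± 0.19), Dgkk (2.69 ± 0.13) and Cyp26b1 (2.67 ± 0.20) were higher at 12 h. Lemd1 (-2.29 ± 0.39), Myh3 (-2.26 ± 0.39), Gadd45b (-2.21 ± 0.12), Dusp14 (-2.14 ± 0.12) and Dnajb1 (-2.12 ± 0.079) were lower. Activity-induced transcription factors (-0.52), mitochondrial genes (-0.11) and microglia markers (-0.27) passed camera downward, and lost their calls at adjusted p between 0.547 and 0.838 with an estimated correlation. Of 100 splits, 3 gave as many genes, the real one included, with 4867 in the highest other, so other groupings of these samples can reach this count. Shuffled residuals gave 1 of 100, the real one, with 2411 in the highest other. That is the smallest share that 100 arrangements can give. The shuffles were chosen after the result was seen, and they cannot show whether the samples came from separate cultures.

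The spiked-in poly-A controls, probe sets that no comparison uses, were higher with IBET858 at 12 h by 0.96 without BDNF and by 0.56 with BDNF (24 probe sets, n = 3 per group). Brighter arrays as the whole cause are argued against, since the hybridisation controls rose by at most 0.397 of the poly-A rise, although they too parted by IBET858 in an exact permutation (two-sided p = 0.005). The same permutation gave 0.005 for the poly-A controls at 12 h, the smallest that 400 arrangements can give, and 0.38 at 2 h. Uneven pipetting into single samples stays open, since the permutation was chosen after the separation was seen and BDNF+IBET858 at 2 h replicate 1 lay 0.64 from its 2 group mates. Less poly-A RNA per amount of total RNA under the inhibitor may explain a rise of at least 0.556 in both arms, but the amount of control RNA added per group is not given in the sources used here, so a difference in that amount cannot be told apart from it.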

How the results depend on the processing

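The largest-variance probe set and the fit without 2 arrays were settings chosen after the data were seen. Of the 16 summary results, each stayed within 1.5 times its value under median centring, cyclic loess, the trended and robust prior, removal of cross-hybridising probe sets, the largest-variance probe set and the fit without 2 arrays. Array weights moved IBET858 against DMSO at 2 h from 2712 genes to 5828, BDNF against DMSO at 2 h from 5068 to 7941 and the interaction at 2 h from 1529 to 2732. By construction they count each array by its spread. The share of higher genes in IBET858 against DMSO at 2 h went from 37.8% to 50.6% with them. The cause was not tested further. Fitting only the groups compared moved IBET858 against DMSO at 2 h to 1725, with fewer samples behind the variance.

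Cyclic loess reversed 3 named genes: Myc with IBET858 at 12 h (0.45), Brd2 with BDNF+IBET858 against IBET858 at 12 h (-0.29) and Egr1 in the difference between times of the IBET858 effect (1.12). The cause was not tested in these genes. Cyclic loess also turned the majority of calls from lower to higher in BDNF+IBET858 against IBET858 at 12 h (40.9% to 50.6% higher), BDNF+IBET858 against BDNF at 12 h (45.2% to 51.1%) and the difference between times of the IBET858 effect (47.6% to 52.7%). Of 329 results for named genes, 315 kept direction and call under cyclic loess, 8 lost the call and 3 gained it. Of 396 results for lists, 353 kept theirs, 33 lost the call and 10 gained it. On simulated values centred per gene, cyclic loess left a median of 49.8% of a true change. Median centring kept 326 and 393 of these results, array weights 311 and 367, removal of cross-hybridising probe sets 328 and 388, the largest-variance probe set 313 and 377, and the fit without 2 arrays 317 and 360. Camera with an estimated correlation kept 305 of 396 list results, and 91 lost the call. Lists called in neither setting count as kept. Of the lists called with the preset correlation, IBET858 against DMSO kept 1 of 12 at 2 h and 4 of 13 at 12 h. BDNF against DMSO kept 5 of 10 and 2 of 7, and the interaction 0 of 12 and 0 of 4.

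With the replicate block, the 16 summary results stayed within 1.5 times, such as 2577 genes for IBET858 against DMSO at 2 h and 2635 for the interaction at 12 h. Arrays with the same number within a time showed little resemblance (36 pairs, r between -0.153 and 0.154). These values gave no clear sign of pairing by number, but they cannot show whether same-numbered samples shared a culture. The block is balanced over the groups and leaves the fold changes as they were. By adjusted p alone, the calls of Hexim1 with BDNF at 12 h (adjusted p = 0.0658) and of Eif2s3y (0.0738) and Kdm5d (0.0591) in the interaction at 12 h were lost.

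Leaving out 1 array at a time, IBET858 against DMSO ranged from 2148 to 2872 genes at 2 h and from 8043 to 9000 at 12 h, BDNF against DMSO from 4198 to 5138 and from 6664 to 6994. BDNF+IBET858 against BDNF ranged from 4153 to 4547 and from 7871 to 8056, and against IBET858 from 2968 to 3350 and from 6181 to 7211. The interaction ranged from 1213 to 1704 and from 2321 to 3107. The differences between times ranged from 5520 to 6338 for IBET858 and from 3956 to 5026 for BDNF. The correlation of the IBET858 effects ranged from 0.593 to 0.723 at 2 h and from 0.781 to 0.809 at 12 h. Genes raised by BDNF and lower with the inhibitor ranged from 724 to 878 and from 1142 to 1431. Of the results for named genes, 2456 kept direction and call, 49 lost the call and 21 gained it. A filter on dim genes and a limit to the more highly expressed genes were not run, since centred values hold no level, and for the same reason signal over background could not be set beside the results.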

Other observations

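The tests chosen only after the result was seen are those of RNA degradation and of neuronal activity on replicate 1 of DMSO at 2 h. The splits and the test of non-neuronal cells were set beforehand.

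Some lists were not described in full above. Cholesterol synthesis genes had a median of -0.13 with IBET858 against DMSO at 2 h (6 of 22 fell and 0 rose, 8 and 2 adjusted over the list alone; camera adjusted p = 0.0184, and adjusted p = 0.436 with an estimated correlation). Without the 2 arrays that stood apart it was -0.013, and the call was lost (adjusted p = 0.313). BET proteins and elongation factors had one of 0.13 with IBET858 at 12 h (13 of 32 rose and 7 fell, 13 and 8 adjusted over the list alone; camera adjusted p = 0.0632), and clock genes one of 0.0073 (camera adjusted p = 0.974). Pan-neuronal markers (0.029; camera adjusted p = 0.00804, and adjusted p = 0.0948 with an estimated correlation), astrocyte markers (0.10; camera adjusted p = 0.00843, and adjusted p = 0.482 with an estimated correlation) and microglia markers (0.16; camera adjusted p = 0.000247, and adjusted p = 0.155 with an estimated correlation) passed camera in BDNF+IBET858 against IBET858 at 2 h. Microglia markers also passed it with BDNF against DMSO at 2 h (0.19; camera adjusted p = 0.00248, and adjusted p = 0.317 with an estimated correlation). Oligodendrocyte markers had a median of 0.046 with IBET858 at 12 h (3 of 17 rose and 2 fell, 2 and 2 adjusted over the list alone; camera adjusted p = 0.816). Of the sex-linked transcripts there, Xist was at 0.31 ± 0.069, Eif2s3y at 0.46 ± 0.10 and Kdm5d at 0.23 ± 0.059 (camera adjusted p = 0.194). Uty was at -0.020 (adjusted p = 0.844) and Tsix at 0.13 (adjusted p = 0.312). The call of Kdm5d was lost with the largest-variance probe set (adjusted p = 0.342).

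For the 8 comparisons of 3 arrays with 3, only 10 splits exist, which are too few for a share under 0.05. In each, 1 of the 10, the real one, gave as many genes. IBET858 against DMSO called 2712 genes at 2 h and 8863 at 12 h, against 0 and 1 in the highest other split by limma. BDNF against DMSO called 5068 and 7463, against 0 and 0. BDNF+IBET858 called 4928 and 8511 against BDNF, with 1 and 0 in the highest other, and 3850 and 7150 against IBET858, with 0 and 3.

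DMSO at 2 h replicate 1 lay apart from replicates 2 and 3, with 169 genes more than 1 log2 unit from their mean. Degraded RNA is argued against, since the difference between the 5-prime and 3-prime probe sets of beta-actin was -0.0054 on that array, within the -0.207 to 0.13 of the other 23. A different share of non-neuronal cells stays open, as astrocyte markers deviated by 0.355, within the -0.224 to 0.362 of the other arrays, while radial glia and progenitor markers deviated by 0.172 (others -0.109 to 0.078) and cell cycle genes by 0.213 (highest other 0.0821). Lower activity of the neurons is a candidate explanation: effector genes deviated by -0.212 (others -0.13 to 0.131) and transcription factors by -0.331 (lowest other -0.173). It leaves much unexplained, since 19 of 33 lists lay outside the other 23 arrays, with interneuron markers at -0.542.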
